A study of Mus musculus with 6 samples.

How the data were processed

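Gene expression was measured in 3 mouse cell lines, named ♂M-1, ♂M-3 and ZM-1, which the labels describe as chromosome transfer embryonic stem cells. The labels do not spell out the ♂M and ZM prefixes. Each line was represented by 2 biological repeats, giving 6 arrays. The cells had been grown on gelatin with LIF and inhibitors of MEK (PD0325901) and of GSK3β (CHIR99021). Total RNA was extracted with Trizol, labelled with biotin by a terminal labelling kit for whole transcripts, and hybridised to a mouse whole-transcript gene array.

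The deposited values are intensity values on a linear scale, 1 per probe set and array. The authors' processing notes name GCOS version 1.4. Background correction, summarisation and normalization between arrays are not given in the sources used here, and detection calls and background levels were not used here. All 35556 probe sets had a value in every array, and 0 values lay below 1. The 6 arrays had nearly equal but not identical distributions, with medians between 67.2 and 71.3 and means between 353 and 367, so no further normalization was applied. Arrays have no counting depth, and the number of arrays limits the precision.

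Gene symbols came from the probe table of the array. Of the probe sets, 21789 carried 1 symbol, 1621 carried several and 12146 were absent from that table. For each gene with a single-symbol probe set, the probe set with the highest mean over the 6 arrays was kept, which gave 19938 genes, 999 of them chosen from more than 1 probe set. Entrez identifiers of 21698 probe sets were found in the RefSeq gene table of GRCm38.p6, which changed 0 symbols. That reference served to assign genes to chromosomes, to order them there and to look up synonyms of list symbols. Ddx3y, Mirg and H19 were not analysed here. Genes with only multi-symbol probe sets were left out of the gene tests, and unnamed probe sets entered a single alternative.

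Values were transformed as log2 of the intensity plus 1. A linear model with 1 mean per line was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, followed by its moderated test. The residual degrees of freedom were 3 and the prior degrees of freedom 6.03. The 3 pairs of lines were compared, and the mean of the ♂M lines was compared with ZM-1. Tests were two-sided, adjusted by the Benjamini-Hochberg method over the 19938 genes, with a threshold of 0.05. A second count also required an absolute log2 difference of at least 1. The p-values measure only the spread between repeats of a line. Because there was 1 ZM line, the difference between the line types and that between the lines cannot be told apart.

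Gene lists, comparisons, tests and the rule for named genes were fixed before the data were examined. The 30 lists were pluripotency, primed epiblast, 2-cell-like, trophectoderm, primitive endoderm, primitive streak and mesoderm, neural, germline, fibroblast, blood and immune cells, maternally expressed imprinted, paternally expressed imprinted, Y-linked, X inactivation and escape, X-linked, ERK targets, Wnt targets, LIF and STAT3 targets, p53 targets, glycolysis, hypoxia, oxidative phosphorylation, cell cycle, cholesterol synthesis, amino acid stress response, interferon response, MHC class I, DNA methylation and Polycomb, Hox, and reference genes. Each list was tested against all other genes with camera at a preset correlation of 0.01 between genes, adjusted over the 30 lists of a comparison. Camera with an estimated correlation was run beside it. That version tests on the 3 residual degrees of freedom, and the preset version on a number near that of the genes. With an estimated correlation camera therefore had little power to call a list, and a lost call does not show correlation between genes. At the preset correlation, the p-values rest on the number of genes more than on the number of arrays. The rotation test fry was also run; it tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. List members past the gene test were counted with p-values adjusted over all genes and again adjusted over the list alone.

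For each pair of lines, the rule named the 8 genes with the largest log2 difference in each direction. These had to pass the threshold with an absolute difference of at least 1, show no overlap between the arrays of the lines, and have a higher line mean above the median of all genes. Predicted genes, clones, olfactory receptors and small RNAs were only counted: 2, 3 and 0 predicted genes or clones were left out in ♂M-1 against ZM-1, ♂M-3 against ZM-1 and ♂M-1 against ♂M-3. The rule added up to 4 called members of each list, and a fixed group of pluripotency, sex chromosome, imprinted and fibroblast genes whatever their test. For the mean of the ♂M lines, it named the 10 largest differences in each direction among genes called against ZM-1 in both lines with the same sign. Leaving out the fold of genes below the lower quartile of the arrays in a compared line was chosen after seeing the data.

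Similarity was described by Pearson correlation across genes and by the root mean square log2 difference for the 15 pairs of arrays; genes are not independent replicates. The differences of ♂M-1 and ♂M-3 from ZM-1 share the ZM-1 arrays. Their correlation, covariance and shared calls were therefore compared with 100 simulated data sets in which no line differed, and with the overlap of independent lists of the same sizes.

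The code was tested on simulated data with 200 changed genes among 19938. In the simulation of ♂M-1 against ZM-1, 89.6% of genes changed by 0.5 log2 units were recovered, and 100% of those changed by 1 or 2 units. Recovery at 0.5 log2 units was 94.0% for ♂M-3 against ZM-1 and 89.6% for ♂M-1 against ♂M-3. The share of unchanged genes among the calls was 5.39%, 8.41% and 4.46% in the simulations of ♂M-1 against ZM-1, ♂M-3 against ZM-1 and ♂M-1 against ♂M-3. A simulated list of 20 genes shifted by 0.5 log2 units was called, and 0 of 30 unshifted lists were. The simulated genes varied independently of each other, so this does not test the preset correlation.

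The alternatives were quantile normalization, median centring of each array, removal of genes below the 25th or the 50th percentile of mean expression, the mean of a gene's probe sets, and a test of every probe set. Others were a variance trend with robust estimation, a fit of the compared lines alone, the repeat number as a block, a threshold of 0.01, each array left out in turn, and, for the mean of the ♂M lines, the line as the replicate. A log2 transform with no offset, and leaving out each array for the shared differences, with simulated data sets of the same arrays, were chosen after seeing the data.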

Results

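The transcriptomes of 3 mouse embryonic stem cell lines made by chromosome transfer, ♂M-1, ♂M-3 and ZM-1, were measured on whole-transcript arrays, with 2 biological repeats per line and 6 arrays in all. The study concerned the reprogramming capacity of the parental pronuclei in the zygote, and its stated design was a comparison of expression profiles between these lines. Median intensity over all probe sets was 68.6 and 68.5 in the ♂M-1 arrays, 69.1 and 67.2 in the ♂M-3 arrays, and 70.6 and 71.3 in the ZM-1 arrays. Intensities are given as the mean ± SD over the 2 repeats of a line. The lower quartile of intensity lay between 23.8 and 25.1 in the 6 arrays. Background levels were not used here, so a named gene whose lower line lay below that range is given by its levels, without a fold.

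All lines carried high levels of the core pluripotency factors. Pou5f1 measured 3711 ± 39.1 (SD, n = 2) in ♂M-1, 3614 ± 75.0 in ♂M-3 and 3875 ± 4.67 in ZM-1. Sox2 measured 2916 ± 275 (SD, n = 2), 2933 ± 24.6 and 2906 ± 103, and Klf4 861 ± 29.0, 902 ± 16.1 and 811 ± 5.04. Esrrb, an orphan nuclear receptor of the naive network, measured 1997 ± 30.9 (SD, n = 2), 2150.0 ± 37.0 and 1961 ± 35.6. These 4 genes passed the test between no pair of lines. The repeats of a line differed by a root mean square of 0.14 log2 units in ♂M-1, 0.14 in ♂M-3 and 0.16 in ZM-1. Between lines, the mean was 0.23 for ♂M-1 and ♂M-3, 0.23 for ♂M-1 and ZM-1, and 0.29 for ♂M-3 and ZM-1. All 6 arrays lay nearest the other repeat of their own line, and ♂M-1 lay about as far from ♂M-3 as from ZM-1.

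The first comparison asked how ♂M-1 differed from ZM-1, and interferon-stimulated genes were among the largest differences, lower in ♂M-1. Oasl2, an oligoadenylate synthetase-like antiviral protein, measured 84.7 ± 0.540 (SD, n = 2) in ♂M-1 and 735 ± 88.1 (SD, n = 2) in ZM-1, 8.55-fold lower in ♂M-1 (log2 difference −3.10, adjusted p = 9.48e-07). Usp18, the protease that removes ISG15 from proteins, was 7.89-fold lower, and Irgm1, an immunity-related GTPase, was 7.04-fold lower. Ifi27 was 4.72-fold lower and Rtp4, another interferon-induced gene, 4.54-fold lower. Irf7, the transcription factor that amplifies interferon production, measured 49.9 ± 0.115 (SD, n = 2) in ♂M-1 and 143 ± 25.4 in ZM-1.

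Of the 11 measured members of the interferon response list, 10 were lower in ♂M-1 than in ZM-1 and 0 were higher; the same counts were obtained adjusted over the list alone. The list was lower by camera (adjusted p = 6.38e-18), with adjusted p = 0.210 with an estimated correlation. The list of MHC class I genes, which carry and load peptide antigens, shifted the same way. In that list 4 of 10 members were lower, or 8 adjusted over the list alone (adjusted p = 6.45e-06, and adjusted p = 0.210 with an estimated correlation). H2-Q4 measured 237 ± 6.54 (SD, n = 2) in ♂M-1 and 429.6 ± 19.1 in ZM-1. The list of blood and immune cell markers shifted with these lists: 2 of 11 were lower in ♂M-1, or 6 adjusted over the list alone (adjusted p = 0.00333, and adjusted p = 0.342 with an estimated correlation). Fcer1g, a signalling subunit of Fc receptors in myeloid cells, measured 42.0 ± 2.10 (SD, n = 2) against 74.8 ± 3.62. Fibroblast markers were not shifted as a list against ZM-1, with 1 of 21 members higher and 3 lower, or 3 and 3 adjusted over the list alone (adjusted p = 0.727).

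**Figure D1:**
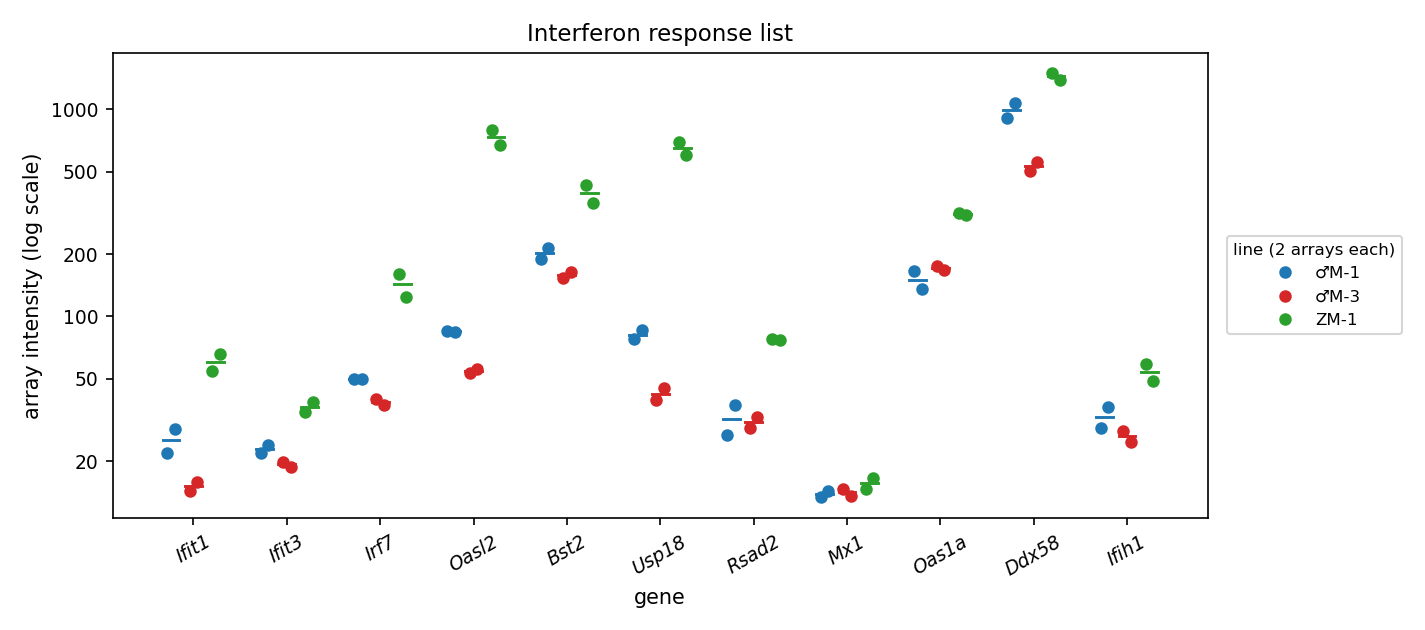
Intensity of the genes of the interferon response list on a log axis (arbitrary units) in the 2 arrays of each line, with points for arrays and horizontal lines for the mean of a line. Oasl2 had a mean of 735 in ZM-1, 84.7 in ♂M-1 and 54.3 in ♂M-3.

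Y-linked genes also separated the lines. Uty, a demethylase-related gene on the Y chromosome, measured 20.8 ± 6.03 (SD, n = 2) in ♂M-1 and 238 ± 11.6 (SD, n = 2) in ZM-1 (adjusted p = 8.42e-06). Eif2s3y, a Y-linked translation initiation factor needed for spermatogonial proliferation, measured 21.7 ± 2.50 (SD, n = 2) in ♂M-1 and 46.5 ± 1.16 in ZM-1 (adjusted p = 3.51e-04). Kdm5d was low in both lines, at 22.4 ± 3.95 and 28.2 ± 3.99 (adjusted p = 0.196). Of the 8 measured Y-linked genes, 4 were lower in ♂M-1 and 0 higher, or 5 and 0 adjusted over the list alone (adjusted p = 1.63e-04, and adjusted p = 0.210 with an estimated correlation). The X inactivation and escape list was higher in ♂M-1, with 1 of 6 members higher, or 2 adjusted over the list alone (adjusted p = 0.0430, and adjusted p = 0.422 with an estimated correlation). That call was lost without ♂M-1 replicate 1 (adjusted p = 0.0600) or 2 (0.0691), without either ♂M-3 array (0.0509), and without ZM-1 replicate 1 (0.108), as well as after quantile normalization (0.232) and among genes above the 25th (0.0876) or the 50th percentile (0.228). Xist, the RNA that silences an X chromosome, measured 129 ± 5.71 (SD, n = 2) in ♂M-1 and 98.2 ± 17.5 in ZM-1 (adjusted p = 0.0977). Klhl13, an X-linked ubiquitin ligase adaptor, was 1.94-fold higher in ♂M-1 (612 ± 28.6 against 315 ± 23.4).

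Among the named genes higher in ♂M-1 than in ZM-1 was the calcium-activated potassium channel Kcnma1. It measured 95.4 ± 2.69 (SD, n = 2) in ♂M-1 and 18.0 ± 2.05 in ZM-1 (adjusted p = 8.48e-06). The matrix proteins Ccdc80 and Efemp1 were 2.72-fold and 2.37-fold higher. The BMP antagonist Grem1 was 2.38-fold higher, the heparan sulfate sulfatase Sulf1 2.09-fold, the ectodysplasin receptor Eda2r 2.36-fold, the neurotrophin receptor Ngfr 2.05-fold, and the augmin subunit Haus4 2.45-fold. In the other direction, the elongin-like gene Elobl was 13.1-fold lower in ♂M-1, the germ cell tudor-domain gene Rnf17 4.24-fold lower, and Dcn, a matrix proteoglycan, 2.68-fold lower. Among imprinted genes, 3 of 14 maternally expressed members were higher and 0 lower, or 4 and 1 adjusted over the list alone (adjusted p = 0.196). Of 24 paternally expressed members, 5 were higher and 1 lower, or 7 and 2 adjusted over the list alone (adjusted p = 0.265). Nnat, a paternally expressed membrane protein, was 2.40-fold lower, and Sfmbt2, a paternally expressed Polycomb-related gene, 1.55-fold higher. Igf2, a growth factor, measured 994 ± 86.7 (SD, n = 2) against 707 ± 7.61, a call lost without ♂M-1 replicate 2 (adjusted p = 0.120) or ZM-1 replicate 1 (0.0502). The noncoding RNA Rian measured 121 ± 0.751 (SD, n = 2) against 74.4 ± 7.35, a call lost without ♂M-1 replicate 1 (adjusted p = 0.0520) or 2 (0.0617). Meg3, a noncoding RNA of the same imprinted region, measured 1330.3 ± 97.3 (SD, n = 2) against 1019 ± 34.6, a call lost without any 1 of the 6 arrays (adjusted p between 0.0636 and 0.214).

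No list of pluripotency, embryonic lineage or germline genes was called between ♂M-1 and ZM-1, although single members passed the gene test. Among them, Neurod1, a neuronal transcription factor, was 1.81-fold lower in ♂M-1 (adjusted p = 0.00326). Pluripotency genes had 1 of 27 members higher, or 2 adjusted over the list alone (adjusted p = 0.296), and Nanog measured 3619 ± 215 (SD, n = 2) against 3361 ± 47.3 (adjusted p = 0.502). Zfp42, a marker of naive pluripotency, measured 291 ± 11.6 (SD, n = 2) against 272 ± 12.0 (adjusted p = 0.523). Col1a1 and Thy1, both fibroblast markers, had adjusted p = 0.522 and 0.955. The germline list had 1 member higher, Tex15 at 1.69-fold, and 1 lower among 18, or 1 and 4 adjusted over the list alone (adjusted p = 0.173). The remaining 20 lists were not called either, with adjusted p between 0.0759 for reference genes and 0.971 for DNA methylation and Polycomb. Without ♂M-1 replicate 1, the 2-cell-like, germline and cell cycle lists were called as lower (each 0.0353), and without ♂M-1 replicate 2 oxidative phosphorylation was called as higher (0.00254). Cell cycle was also called after quantile normalization (0.00229) and among genes above the 50th percentile (0.0412). For primitive endoderm, neural, fibroblast, ERK targets, hypoxia, cholesterol synthesis, and DNA methylation and Polycomb, the median, the mean and the test differed in sign.

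In total, 882 genes passed the test between ♂M-1 and ZM-1, 378 higher and 504 lower in ♂M-1, and 77 of them differed by at least 1 log2 unit, 12 higher and 65 lower. After median centring of the arrays, 62.0% of 1014 called genes were higher in ♂M-1, against 42.9% before. The count fell to 369 without ♂M-1 replicate 1, to 235 without ♂M-1 replicate 2 and to 578 without ZM-1 replicate 2.

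♂M-3 differed from ZM-1 in more genes, and among the named genes the 4 largest differences toward lower expression in ♂M-3 were in interferon-stimulated genes. Irgm1 measured 32.9 ± 9.58 (SD, n = 2) in ♂M-3 and 725 ± 41.9 (SD, n = 2) in ZM-1, 21.9-fold lower (log2 difference −4.45, adjusted p = 1.45e-06). Usp18 was 15.1-fold lower, Oasl2 13.3-fold lower and Ifi27 7.87-fold lower. Lgals3bp, a secreted glycoprotein, was 6.11-fold lower. Trim12a, a member of the TRIM family, measured 13.7 ± 2.35 (SD, n = 2) against 97.9 ± 17.4 (adjusted p = 3.34e-05). Of 11 interferon response genes, 10 were lower and 0 higher, counts that were the same adjusted over the list alone (adjusted p = 2.01e-15, and adjusted p = 0.180 with an estimated correlation). MHC class I genes had 7 of 10 members lower, also 7 adjusted over the list alone (adjusted p = 7.49e-07, and adjusted p = 0.180 with an estimated correlation). B2m, the invariant light chain of these molecules, measured 741 ± 1.17 (SD, n = 2) in ♂M-3 and 1376 ± 21.0 in ZM-1. The list of blood and immune cell markers shifted with them, with 5 of 11 lower, or 6 adjusted over the list alone (adjusted p = 0.00176, and adjusted p = 0.280 with an estimated correlation).

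The fibroblast list was lower in ♂M-3 as well. Dcn measured 104 ± 11.3 (SD, n = 2) in ♂M-3 and 571 ± 35.3 in ZM-1, 5.44-fold lower. The mesenchymal transcription factors Twist2 and Prrx1 were 2.23-fold and 1.65-fold lower, the matrix protease Mmp2 2.19-fold, the collagen Col1a1 1.49-fold and the surface protein Thy1 1.42-fold. Of 21 members, 12 were lower and 1 higher, or 13 and 1 adjusted over the list alone (adjusted p = 7.84e-07, and adjusted p = 0.180 with an estimated correlation). In these cultures 18 of the 21 members lay above the median of all genes. The list of p53 targets shifted the same way, with 9 of 16 lower and 2 higher, or 10 and 2 adjusted over the list alone (adjusted p = 0.00148, and adjusted p = 0.280 with an estimated correlation). Plk2, a stress-induced kinase, was 2.18-fold lower, Pmaip1, a proapoptotic BH3-only gene, 1.93-fold lower and the antiproliferative gene Btg2 1.82-fold lower, whereas Eda2r was 2.60-fold higher.

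As lists, pluripotency genes were higher and primed epiblast genes lower in ♂M-3, with most members of each list not past the gene test. Zfp42 measured 671 ± 3.77 (SD, n = 2) in ♂M-3 and 272 ± 12.0 (SD, n = 2) in ZM-1, 2.47-fold higher (adjusted p = 2.37e-05). Dppa3, a maternal factor also expressed in naive cells, was 1.77-fold higher and the AKT coactivator Tcl1 1.68-fold higher. Nanog measured 4086 ± 5.49 (SD, n = 2) against 3361 ± 47.3 (adjusted p = 0.0384), a call lost without ♂M-3 replicate 1 (adjusted p = 0.148) or 2 (0.161) and without ZM-1 replicate 1 (0.0806) or 2 (0.120). Of 27 pluripotency genes, 9 were higher and 2 lower, or 10 and 2 adjusted over the list alone (adjusted p = 0.00608, and adjusted p = 0.320 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.110) and among genes above the 50th percentile (0.203). Primed epiblast genes had 4 of 15 lower, the same adjusted over the list alone (adjusted p = 0.0184, and adjusted p = 0.557 with an estimated correlation). Fgf5, a growth factor of the primed epiblast, was 1.62-fold lower and the de novo methyltransferase Dnmt3a 1.55-fold lower. The primed call was lost without ♂M-3 replicate 1 (adjusted p = 0.0508) or ZM-1 replicate 1 (0.0715). LIF and STAT3 targets had 4 of 10 higher, the same adjusted over the list alone (adjusted p = 0.00484, and adjusted p = 0.360 with an estimated correlation), a call lost among genes above the 50th percentile (0.0619). Bcl3 was 2.22-fold higher and Socs3, the feedback inhibitor of the pathway, 1.49-fold.

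As a list, oxidative phosphorylation was higher in ♂M-3, with 6 of 27 members higher and 21 not past the gene test, the same adjusted over the list alone (adjusted p = 7.99e-04, and adjusted p = 0.394 with an estimated correlation). Its median log2 difference was 0.181, against 0.139 for the 7 measured reference genes (adjusted p = 0.180 by camera). All members of both lists lay above the median of all genes, so the shift may not be particular to oxidative phosphorylation. The pluripotency list and the LIF and STAT3 list, with medians of 0.152 and 0.168, share that limit. Cyc1 of respiratory complex III measured 1697 ± 192 (SD, n = 2) against 1080.4 ± 6.11. Ndufa9, a subunit of complex I, was 1.49-fold higher. Primitive endoderm genes had 5 of 19 lower and 1 higher, or 6 and 1 adjusted over the list alone (adjusted p = 0.0426, and adjusted p = 0.394 with an estimated correlation). The basement membrane gene Lamb1 was 1.66-fold lower and Lama1, another laminin chain, 2.11-fold higher. That call was lost without ♂M-3 replicate 1 (adjusted p = 0.0866) or ZM-1 replicate 2 (0.251), and after quantile normalization (0.126).

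Eif2s3y measured 391 ± 7.20 (SD, n = 2) in ♂M-3 and 46.5 ± 1.16 (SD, n = 2) in ZM-1, 8.27-fold higher (adjusted p = 5.41e-07). Uty measured 387 ± 4.36 (SD, n = 2) against 238 ± 11.6, a call lost without ♂M-3 replicate 1 or 2 or ZM-1 replicate 2. Its log2 difference of 0.70 stayed between 0.65 and 0.75 whichever array was left out. Of 8 Y-linked genes, 3 were higher and 0 lower, or 4 and 0 adjusted over the list alone (adjusted p = 0.0661). This list was called without ♂M-3 replicate 2 (0.0411) or ZM-1 replicate 2 (0.0284), after quantile normalization (0.0447) and among genes above the 25th percentile (0.0176). Kdm5d and Xist had adjusted p = 0.144 and 0.374. Among imprinted genes, the maternally expressed list had 1 of 14 higher and 1 lower, or 3 and 2 adjusted over the list alone (adjusted p = 0.799), and its median and mean differed in sign. The paternally expressed list had 7 of 24 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.423). Plagl1, a zinc finger gene that inhibits growth, was 2.28-fold higher and Mest 1.63-fold higher, while Nnat was 2.13-fold lower. Rian was 1.83-fold higher, and Meg3 and Igf2 did not pass (adjusted p = 0.0517 and 0.115). The Hox list had 3 of 37 higher and 2 lower, or 2 and 2 adjusted over the list alone (adjusted p = 0.510), with Hoxc12 1.84-fold higher.

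Among the named genes higher in ♂M-3, the largest differences were in Lrrc31, then Eif2s3y, then Rpl10l. Lrrc31, a leucine-rich repeat gene, measured 352 ± 38.8 (SD, n = 2) against 34.9 ± 2.20, and Rpl10l, a ribosomal protein retrogene used in male meiosis, 800.2 ± 42.5 against 187 ± 11.7. The Rac exchange factor Prex2 was 4.01-fold higher, the sodium pump regulator Fxyd6 3.27-fold, and the ganglioside synthase St8sia1 2.93-fold. Obox6, an oocyte homeobox gene, was 5.88-fold lower and Olig2, a neural transcription factor, 3.11-fold lower. ERK targets were split, with 3 of 17 higher and 6 lower, or 4 and 7 adjusted over the list alone (adjusted p = 0.203). So were genes of the amino acid stress response, with 6 of 17 higher and 2 lower, or 9 and 3 adjusted over the list alone (adjusted p = 0.0844). In the remaining lists, the smallest adjusted p was 0.102 for glycolysis and the largest 0.689 for hypoxia, and germline was called among genes above the 50th percentile (0.0376).

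In total, 3162 genes passed between ♂M-3 and ZM-1, 1726 higher and 1436 lower in ♂M-3, and 183 differed by at least 1 log2 unit, 57 higher and 126 lower. After median centring, 70.8% of 3704 called genes were higher, against 54.6% before. The count fell to 1364 without ♂M-3 replicate 1, to 1301 without ♂M-3 replicate 2 and to 2081 without ZM-1 replicate 2.

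The ♂M-1 and ♂M-3 lines, whose names share a prefix, also differed from each other, and Y-linked genes were among the genes that differed. Uty measured 20.8 ± 6.03 (SD, n = 2) in ♂M-1 and 387 ± 4.36 in ♂M-3 (adjusted p = 3.83e-06). Eif2s3y measured 21.7 ± 2.50 (SD, n = 2) and 391 ± 7.20 (adjusted p = 1.09e-07). Uba1y, a Y-linked ubiquitin-activating enzyme, measured 46.8 ± 0.743 (SD, n = 2) in ♂M-1 and 103 ± 1.78 (SD, n = 2) in ♂M-3, 2.17-fold lower. Kdm5d did not pass (adjusted p = 0.954), at 22.4 ± 3.95 (SD, n = 2) and 22.6 ± 0.262. Of 8 Y-linked genes, 4 were lower in ♂M-1 and 0 higher, or 5 and 1 adjusted over the list alone (adjusted p = 3.51e-05, and adjusted p = 0.178 with an estimated correlation). Xist measured 129 ± 5.71 (SD, n = 2) in ♂M-1 and 86.5 ± 5.47 in ♂M-3 (adjusted p = 0.0224). That call was lost without ♂M-1 replicate 1 (0.0833) or 2 (0.182) and without ♂M-3 replicate 1 (0.0761) or 2 (0.149). The X inactivation list had 2 of 6 higher, the same adjusted over the list alone (adjusted p = 0.205), and X-linked genes 1 of 27 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.561).

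**Figure D2:**
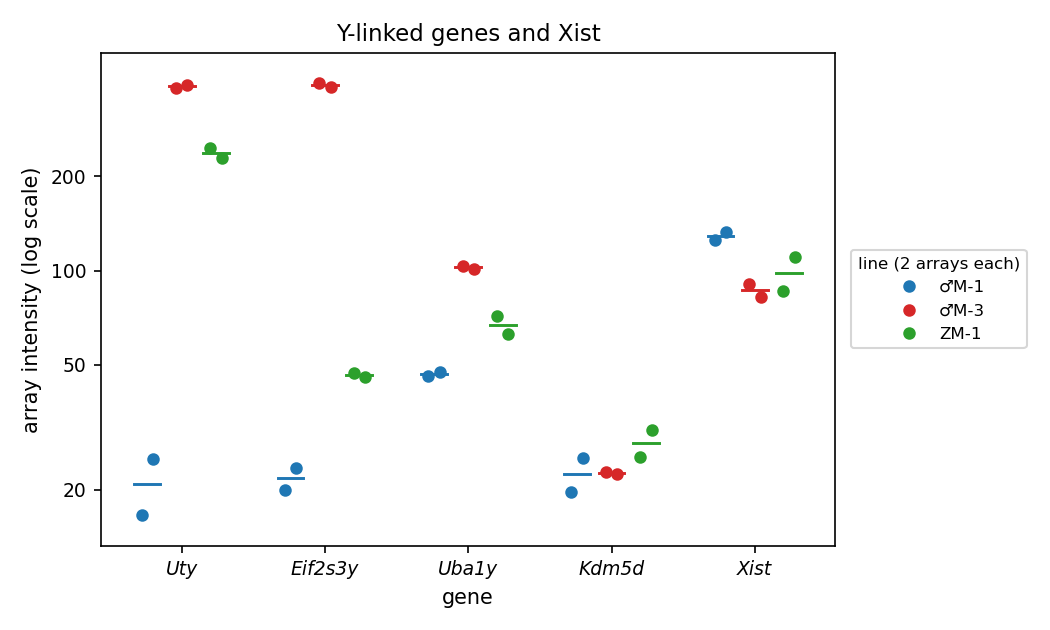
Intensity of Y-linked genes and Xist on a log axis (arbitrary units) in the 2 arrays of each line, with points for arrays and horizontal lines for the mean of a line. Uty had a mean of 20.8 in ♂M-1, 387 in ♂M-3 and 238 in ZM-1, and Eif2s3y 21.7, 391 and 46.5.

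As lists, fibroblast markers and p53 targets were higher in ♂M-1 than in ♂M-3, with 10 of 21 and 9 of 16 members not past the gene test. Of 21 fibroblast genes, 11 were higher and 0 lower, or 13 and 1 adjusted over the list alone (adjusted p = 9.00e-10, and adjusted p = 0.178 with an estimated correlation). Col1a1 measured 886 ± 30.5 (SD, n = 2) in ♂M-1 and 549.6 ± 52.9 in ♂M-3, and Lox, a collagen cross-linking enzyme, 1491 ± 114 against 882 ± 27.1. Dcn was 2.03-fold higher. Thy1 was 1.43-fold higher, a call lost without ♂M-1 replicate 2 (adjusted p = 0.0543) or ♂M-3 replicate 2 (0.0510). Of 16 p53 targets, 6 were higher and 1 lower, or 12 and 2 adjusted over the list alone (adjusted p = 5.91e-07, and adjusted p = 0.178 with an estimated correlation). Pmaip1 was 2.68-fold higher, Plk2 2.22-fold, Perp, a desmosomal gene, 1.62-fold and Phlda3, an AKT repressor, 1.59-fold.

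As lists, interferon-stimulated and MHC class I genes were higher in ♂M-1 than in ♂M-3, with 7 of 11 and 6 of 10 members not past the gene test. Usp18 was 1.91-fold higher and the cytosolic RNA sensor Ddx58 1.86-fold, and Irgm1, which is not in the list, 3.10-fold. In the interferon list 4 of 11 members were higher, or 7 adjusted over the list alone (adjusted p = 2.49e-05, and adjusted p = 0.282 with an estimated correlation). In the MHC class I list 4 of 10 were higher, the same adjusted over the list alone (adjusted p = 0.00335, and adjusted p = 0.282 with an estimated correlation). The peptide transporter Tap1 was 1.58-fold and B2m 1.56-fold higher. The list of blood and immune cell markers was not called here, with 0 of 11 called, also 0 adjusted over the list alone (adjusted p = 0.274).

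As lists, pluripotency genes were lower and primed epiblast genes higher in ♂M-1 than in ♂M-3, again with most members not past the gene test. Zfp42 measured 291 ± 11.6 (SD, n = 2) in ♂M-1 and 671 ± 3.77 (SD, n = 2) in ♂M-3, 2.30-fold lower (adjusted p = 8.53e-05), whereas Nanog did not pass (adjusted p = 0.249). Of 27 pluripotency genes, 4 were lower and 2 higher, the same adjusted over the list alone (adjusted p = 0.0181, and adjusted p = 0.337 with an estimated correlation). Of 15 primed epiblast genes, 5 were higher, or 7 with 1 lower adjusted over the list alone (adjusted p = 0.00118, and adjusted p = 0.436 with an estimated correlation). Dnmt3b, a de novo methyltransferase, was 1.63-fold higher and the tight junction gene Cldn6 1.64-fold. LIF and STAT3 targets had 2 of 10 lower, or 3 adjusted over the list alone (adjusted p = 0.0172, and adjusted p = 0.349 with an estimated correlation). Oxidative phosphorylation had 1 of 27 lower, the same adjusted over the list alone (adjusted p = 0.0116, and adjusted p = 0.506 with an estimated correlation). Targets of ERK had 5 of 17 higher, or 7 with 1 lower adjusted over the list alone (adjusted p = 0.00975, and adjusted p = 0.509 with an estimated correlation).

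Primitive endoderm genes had 4 of 19 higher and 1 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.0226, and adjusted p = 0.346 with an estimated correlation). Lama1 was 2.07-fold lower and Lamb1 1.46-fold higher in ♂M-1. Among neural genes, 1 of 14 was higher, or 3 adjusted over the list alone (adjusted p = 0.0283, and adjusted p = 0.337 with an estimated correlation), with Olig2 4.11-fold higher. Wnt targets had 2 of 15 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.0266, and adjusted p = 0.337 with an estimated correlation). Cholesterol synthesis had 0 of 16 called, also 0 adjusted over the list alone, and was lower as a list (adjusted p = 0.0266, and adjusted p = 0.527 with an estimated correlation). The amino acid stress response had 4 of 17 lower, or 8 with 2 higher adjusted over the list alone (adjusted p = 0.0181, and adjusted p = 0.509 with an estimated correlation). Without ♂M-1 replicate 2, the calls of pluripotency (adjusted p = 0.0615), neural (0.0630), ERK (0.0810), Wnt (0.0652), LIF and STAT3 (0.0522), oxidative phosphorylation (0.222), cholesterol (0.104) and amino acid stress (0.0810) were lost, leaving 7 of 15 list calls. Primitive endoderm was lost without ♂M-1 replicate 1 (0.0522), Wnt targets without ♂M-3 replicate 1 (0.0835), and neural (0.0539), LIF and STAT3 (0.0533) and cholesterol (0.126) without ♂M-3 replicate 2. After quantile normalization, primitive endoderm (0.0585), neural (0.0643) and cholesterol (0.0632) were lost. Among genes above the 50th percentile, pluripotency (0.105), neural (0.172), Wnt, LIF and STAT3, oxidative phosphorylation (each 0.0576) and cholesterol (0.105) were lost.

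The germline list had 1 of 18 higher and 2 lower, or 2 and 4 adjusted over the list alone (adjusted p = 0.887), with Tex15, a factor of meiotic repair, 2.11-fold higher and Hormad2, a meiotic axis gene, 1.91-fold lower in ♂M-1. Paternally expressed imprinted genes had 2 of 24 higher and 3 lower, or 6 and 5 adjusted over the list alone (adjusted p = 0.972). Peg10 was 1.57-fold higher, Plagl1 1.73-fold lower and Inpp5f 1.80-fold lower, and Meg3, Rian and Igf2 did not pass (adjusted p = 0.588, 0.394 and 0.112). Maternally expressed genes had 1 of 14 higher and 1 lower, or 2 and 1 adjusted over the list alone (adjusted p = 0.178). Other single genes with large differences were Kcnma1, 3.49-fold higher in ♂M-1, the retroviral restriction gene Fv1, 2.81-fold higher, and Ube2l6, the conjugating enzyme of ISG15, 3.23-fold higher. Lrrc31 was 10.4-fold lower, Rpl10l 4.61-fold lower, and Ly75, an endocytic receptor of dendritic cells, 3.76-fold lower. Among the remaining lists, the adjusted p ran from 0.119 for glycolysis to 0.972 for trophectoderm. Without ♂M-1 replicate 1, glycolysis (0.0111), hypoxia (0.0256) and maternally expressed imprinted genes (0.0492) were called. For trophectoderm, germline, paternally expressed imprinted genes and Hox, the median, the mean and the test differed in sign.

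In total, 1303 genes passed between ♂M-1 and ♂M-3, 642 higher and 661 lower in ♂M-1, and 82 differed by at least 1 log2 unit, 39 higher and 43 lower. The count fell to 762 without ♂M-1 replicate 1, 357 without ♂M-1 replicate 2, 467 without ♂M-3 replicate 1 and 419 without ♂M-3 replicate 2.

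The mean of the ♂M lines was compared with ZM-1 to find differences that the ♂M lines had in common. Interferon-stimulated genes were lower in both ♂M lines, with 10 of the 11 list members called in each. Irgm1 was 12.4-fold lower in the mean, Usp18 10.9-fold, Oasl2 10.6-fold and Ifi27 6.09-fold. Oas2, which activates an antiviral ribonuclease, measured 73.4 ± 1.30 (SD, n = 2) in ♂M-1, 72.3 ± 2.28 in ♂M-3 and 296 ± 17.1 in ZM-1. Parp12, an interferon-induced ADP-ribosyltransferase, measured 233 ± 16.0 (SD, n = 2), 161 ± 1.74 and 762 ± 55.1. Elobl was 9.55-fold lower and Rnf17 4.13-fold lower. Higher in both ♂M lines were Kcnma1, at 95.4 ± 2.69 (SD, n = 2) in ♂M-1, 26.7 ± 3.23 in ♂M-3 and 18.0 ± 2.05 in ZM-1, and Eda2r, 2.48-fold in the mean, Klhl13, 2.24-fold, Sulf1, 2.15-fold, and the circadian repressor Bhlhe40, 2.09-fold.

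Of 11 interferon response genes, 10 were lower in the mean, the same adjusted over the list alone (adjusted p = 3.51e-17, and adjusted p = 0.185 with an estimated correlation). Of 10 MHC class I genes, 7 were lower, or 8 adjusted over the list alone (adjusted p = 2.42e-07, and adjusted p = 0.185 with an estimated correlation). The list of blood and immune cell markers shifted with them, with 5 of 11 lower, or 7 adjusted over the list alone (adjusted p = 0.00137, and adjusted p = 0.292 with an estimated correlation). The fibroblast list was lower in the mean, with 8 of 21 lower and 1 higher, or 9 and 1 adjusted over the list alone (adjusted p = 6.20e-04, and adjusted p = 0.292 with an estimated correlation). Oxidative phosphorylation had 3 of 27 higher, or 5 adjusted over the list alone (adjusted p = 0.00281, and adjusted p = 0.493 with an estimated correlation). Pluripotency had 6 of 27 higher, or 7 adjusted over the list alone (adjusted p = 0.0272, and adjusted p = 0.493 with an estimated correlation). LIF and STAT3 targets had 3 of 10 higher, the same adjusted over the list alone (adjusted p = 0.0206, and adjusted p = 0.493 with an estimated correlation). These last 4 lists were called against ZM-1 in ♂M-3 but not in ♂M-1, where the adjusted p was 0.727 for fibroblast, 0.0966 for oxidative phosphorylation, 0.296 for pluripotency and 0.196 for LIF and STAT3 targets. Their calls in the mean therefore do not show a difference that the ♂M lines had in common. After quantile normalization the calls of oxidative phosphorylation (adjusted p = 0.154), pluripotency (0.421) and LIF and STAT3 targets (0.148) were lost. The pluripotency call was also lost without ♂M-1 replicate 1 (0.0638) or ZM-1 replicate 2 (0.0969). Among genes above the 50th percentile, oxidative phosphorylation (0.139), pluripotency (0.373) and LIF and STAT3 targets (0.176) were lost, and above the 25th percentile the last 2 were (0.0967 and 0.0599). The other 23 lists were not called, from 0.0743 for p53 targets to 0.990 for hypoxia. The p53 list was called without ♂M-1 replicate 2 (0.0463), after quantile normalization (0.0180) and among genes above the 50th percentile (0.0267), and cell cycle after quantile normalization (0.0126). For maternally expressed imprinted genes, Wnt targets and hypoxia, the median, the mean and the test differed in sign.

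**Figure D3:**
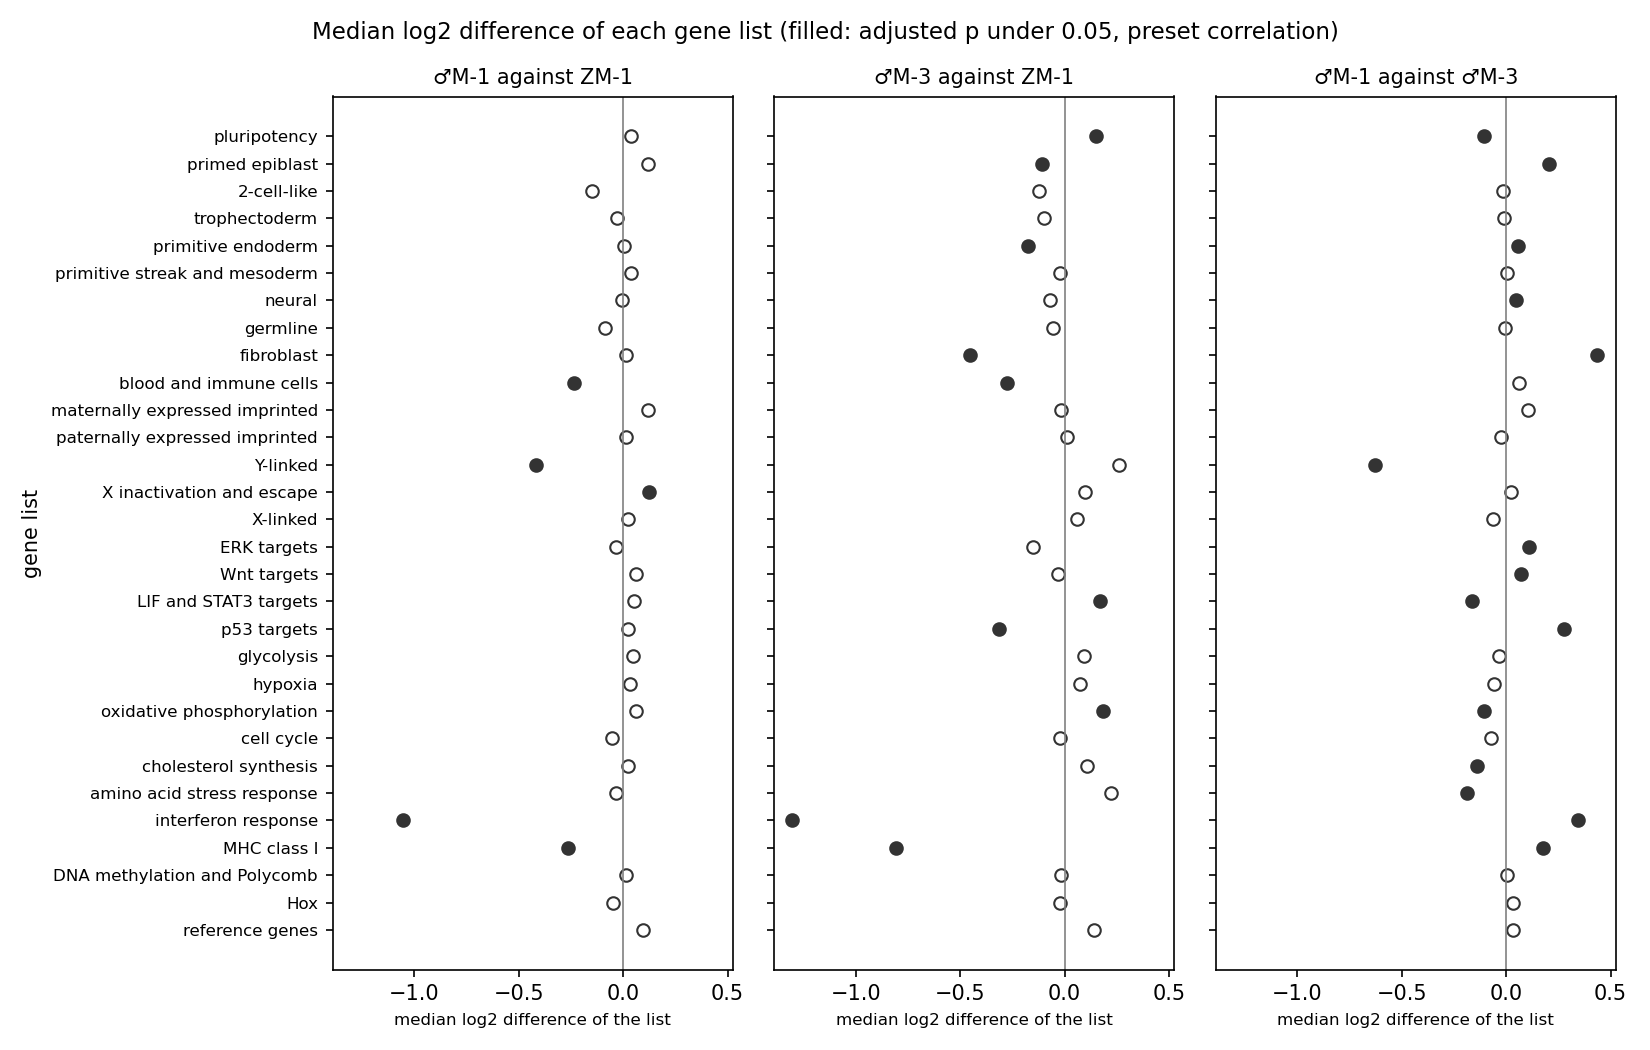
Median log2 difference of the measured members of each of the 30 gene lists in the 3 comparisons between lines, with filled points for lists called by camera at the preset correlation. The interferon response list lies at −1.06 for ♂M-1 against ZM-1, −1.30 for ♂M-3 against ZM-1 and 0.34 for ♂M-1 against ♂M-3.

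In the mean, 2330 genes passed, 1202 higher and 1128 lower than in ZM-1, and 95 differed by at least 1 log2 unit, 14 higher and 81 lower. With the line in place of the array as the replicate, limma called 0 genes. After median centring, 71.5% of 2868 called genes were higher, against 51.6% before. Leaving out 1 array moved the count to 1390 (♂M-1 replicate 1), 1489 (♂M-1 replicate 2), 1390 (♂M-3 replicate 1), 1331 (♂M-3 replicate 2), 1493 (ZM-1 replicate 1) and 1221 (ZM-1 replicate 2).

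The differences of ♂M-1 and ♂M-3 from ZM-1 were then compared with each other; both use the ZM-1 arrays. Across genes their covariance was 0.0361, against a mean of 0.00437 in simulated data sets in which no line differed, a difference of 0.0318 that ranged from 0.0296 to 0.0365 with 1 array left out. Their correlation was 0.647, against a simulated mean of 0.499 and a highest value of 0.516. It was 0.566 without ♂M-1 replicate 1 (simulated mean 0.408, highest 0.422), 0.690 without ZM-1 replicate 1 (0.667 and 0.676) and 0.675 without ZM-1 replicate 2 (0.666 and 0.676), the last within the simulated range. The simulated lines did not differ at all. Lines that all differ from each other, or ZM-1 differing alone, would also raise the covariance and the shared calls. The excess therefore does not show that the ♂M lines are more alike than other lines. Both lines were higher than ZM-1 in 231 genes and lower in 358. Independent lists of these sizes would share 32.7 and 36.3, a baseline that ignores the shared ZM-1 arrays. The simulated data sets, with at most 1 such gene of each kind, hold almost no calls and do not show how many calls are shared by chance. Part of these counts may therefore come from the shared arrays. The 589 shared calls became 239 without ♂M-1 replicate 1, 191 without ♂M-1 replicate 2, 332 without ♂M-3 replicate 1 and 340 without ♂M-3 replicate 2. A further 20 genes were called in both lines in opposite directions.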

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

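The results below were singled out because ♂M-1 and ♂M-3 were called against ZM-1 in opposite directions. The direct difference is then the sum of both sizes, so its test adds no separate support. The tests of a mixture of cells, of a swapped array and of a second active X chromosome were chosen after the result was seen.

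Uty measured 20.8 ± 6.03 (SD, n = 2) in ♂M-1, 387 ± 4.36 in ♂M-3 and 238 ± 11.6 in ZM-1, and Eif2s3y 21.7 ± 2.50, 391 ± 7.20 and 46.5 ± 1.16. Their ♂M-1 levels lay below the lower quartile of the arrays and background levels were not used here. The log2 differences ♂M-1 minus ♂M-3 of −4.18 for Uty (adjusted p = 3.83e-06) and −4.11 for Eif2s3y (adjusted p = 1.09e-07) therefore give the direction but no settled size. Given as the same log2 difference, with the differences of ♂M-1 and then ♂M-3 from ZM-1, Uba1y stood at −1.12 (−0.51 and 0.61, adjusted p = 1.73e-04 for the direct difference). The endocytic receptor gene Ly75 stood at −1.91 (−0.78 and 1.13, adjusted p = 8.44e-05). The cytoskeletal adaptor gene Obsl1 stood at 1.68 (0.59 and −1.09, adjusted p = 1.02e-04). The anion exchanger gene Slc4a3 stood at 1.53 (0.72 and −0.81, adjusted p = 5.13e-05), and Tex15 at 1.08 (0.76 and −0.32, adjusted p = 1.73e-04). Cldn6 stood at 0.72 (0.43 and −0.29, adjusted p = 8.92e-04).

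The direct difference between ♂M-1 and ♂M-3 kept its sign for these 8 genes whichever array was left out. A called direct difference was part of their selection, so this adds no separate support. Some calls against ZM-1 did not hold with 1 array left out. In ♂M-1, Cldn6 was lost without ♂M-1 replicate 1 (adjusted p = 0.0935), ♂M-1 replicate 2 (0.0755) or ZM-1 replicate 2 (0.0578). Uba1y was lost there without ♂M-1 replicate 1 (0.0809) or 2 (0.0829), and Obsl1 without ♂M-1 replicate 2 (0.124) or ZM-1 replicate 2 (0.0824). In ♂M-3, Cldn6 was lost without ♂M-3 replicate 1 (0.132) or 2 (0.136) and ZM-1 replicate 1 (0.0987) or 2 (0.0648), and Tex15 without the same arrays (0.157, 0.0885, 0.0793 and 0.0746). Uty was lost in ♂M-3 without ♂M-3 replicate 1 or 2 or ZM-1 replicate 2. Its log2 difference from ZM-1 there stayed between 0.65 and 0.75 whichever array was left out, so its size did not rest on 1 array. The lines share 1 estimate of the spread, which the low ♂M-1 arrays, at 16.6 and 25.1, also enter.

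In ZM-1, Uty reached 59.2% of its level in ♂M-3 and Eif2s3y 6.70%, each counted above the level in ♂M-1. A single share of cells with a Y chromosome in ZM-1 would give these genes like shares, if both probe sets read the Y chromosomes of ZM-1 and ♂M-3 alike. Their ratio of 8.85 argues against such a mixture only under that condition. A sequence variant under the probes could also give unlike shares. In the ZM-1 repeats the shares were 61.5% and 57.0% for Uty and 6.92% and 6.47% for Eif2s3y. With no level subtracted they were 61.4% and 11.9% in the mean. A single swapped array is argued against by the 0 arrays that lay nearer another line than the other repeat of their own line. The median of X-linked genes minus that of autosomal genes was −0.0296 log2 units for ♂M-1 minus ♂M-3, which argues against a second active X chromosome in ♂M-1. What stays open is a difference between the lines in the content or activity of the Y chromosome, or a sequence variant under the probes, with or without a mixture. Neither the difference nor the variant was tested.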

How the results depend on the processing

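All alternatives were set out before the data were examined except the log2 transform with no offset and the left-out arrays for the shared differences. In the settings below, counts follow the order ♂M-1 against ZM-1, ♂M-3 against ZM-1, ♂M-1 against ♂M-3 and the mean of the ♂M lines against ZM-1. No gene called in any setting had the opposite sign among the genes called in the main setting. Of 4827 checks of 289 named gene results, 4216 kept their side of the threshold, 597 lost a call, 14 gained one and 0 reversed. Of the list results, 542 of 588 kept their side in other settings and 686 of 720 with 1 array left out. These tallies include results not called in the main setting, which have no call to lose. Many named calls were lost with some array left out, so a fold given with no stated loss may still depend on 1 array. The other settings of the lists leave out the estimated correlation, with which 37 list calls were lost. On 3 residual degrees of freedom that version had little power, so these losses do not tell which lists hold. Where an array is left out, the lone array of its line is assumed to vary like the other lines. Background and detection levels were not used here, so the signal at which a gene counts as expressed is unknown.

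The counts of called genes (882, 3162, 1303 and 2330) became 275, 2027, 442 and 1321 when every probe set was tested (35556 tests in place of 19938), and 291, 1266, 472 and 788 at a threshold of 0.01. With a variance trend and robust estimation, the first and the third became 1694 and 1997; the cause was not tested. With the line as the replicate, 0 genes were called in the mean, and 0 with at least 1 log2 unit, on 1 residual degree of freedom. With at least 1 log2 unit, the counts (77, 183, 82 and 95) became 35, 108, 53 and 44 among genes above the 50th percentile, where fewer genes are tested. With every probe set, the last 3 became 334, 133 and 175. The other settings left these counts within 1.5 times, apart from left-out arrays.

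With 1 array left out, and so fewer samples, the counts ranged from 235 to 633, from 1301 to 2749, from 357 to 1495 and from 1221 to 1493. Those with at least 1 log2 unit ranged from 76 to 88, from 183 to 195, from 69 to 103 and from 96 to 103. The numbers of lists called (5, 10, 15 and 7) ranged from 4 to 7, 8 to 11, 7 to 17 and 6 to 8. With an estimated correlation, 0, 0, 0 and 0 lists were called, with smallest adjusted p of 0.210, 0.180, 0.178 and 0.185. Among genes above the 50th percentile, 3 lists were called in the first comparison, 8 in the third and 4 in the mean. The rotation test called 6, 13, 10 and 7 lists. Between ♂M-1 and ♂M-3 it lost primed epiblast (adjusted p = 0.0719), primitive endoderm (0.110), ERK targets (0.136), oxidative phosphorylation and cholesterol (each 0.110). It also lost primed epiblast in ♂M-3 against ZM-1 (0.0850) and oxidative phosphorylation in the mean (0.0936). It gained reference genes against ZM-1 in ♂M-1 (0.0359), ♂M-3 (0.0180) and the mean (0.0213). In ♂M-3 against ZM-1 it also gained neural (0.0255), Y-linked (0.00762) and X-linked genes (0.0260).

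The root mean square difference of ♂M-1 and ZM-1 was 0.233, and 0.229 after quantile normalization, 0.236 above the 50th percentile and 0.288 with every probe set. For ♂M-3 and ZM-1 it was 0.292, and 0.287, 0.314 and 0.337. For ♂M-1 and ♂M-3 it was 0.232, and 0.251 above the 50th percentile and 0.271 with every probe set; the cause was not tested. The 589 shared calls became 223 with every probe set, where more probe sets are tested. With 1 array left out they ranged from 191 to 464, and the correlation of 0.647 ranged from 0.566 to 0.690, while its simulated mean with no line differing ranged from 0.407 to 0.667.

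Repeats share only a number between lines, and their differences correlated across genes by −0.03 for ♂M-1 and ♂M-3, 0.07 for ♂M-1 and ZM-1 and −0.10 for ♂M-3 and ZM-1. With the repeat number as a block, 686, 2768, 1070 and 1893 genes were called, and the X inactivation and escape list of ♂M-1 against ZM-1 was no longer called (adjusted p = 0.0516). A pairing was not used.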

Other observations

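Some members of the ERK target, neural and trophectoderm lists differed from ZM-1 in both ♂M lines, although none of these lists was called against ZM-1. Between ♂M-1 and ♂M-3, the ERK list was called with adjusted p = 0.00975 and the neural list with 0.0283, against adjusted p = 0.509 and 0.337 with an estimated correlation, and both calls were lost without ♂M-1 replicate 2 (0.0810 and 0.0630). The neural call was also lost without ♂M-3 replicate 2 (0.0539). Ier3, an immediate early gene induced by ERK signalling, measured 161 ± 3.56 (SD, n = 2) in ♂M-1, 158 ± 11.6 in ♂M-3 and 85.7 ± 5.0 in ZM-1, 1.87-fold and 1.83-fold higher (adjusted p = 6.53e-04 and 2.74e-04). Of the 17 ERK targets, 1 was called as higher and 0 as lower in ♂M-1, and 3 and 6 in ♂M-3. Neurod1, a neuronal transcription factor, was 1.81-fold lower in ♂M-1 and 2.35-fold lower in ♂M-3. Tfap2c, a transcription factor of trophectoderm and germ cells, measured 333 ± 20.3 (SD, n = 2) in ♂M-1, 349 ± 4.53 in ♂M-3 and 195 ± 26.0 in ZM-1, and the ♂M-1 call was lost without ♂M-1 replicate 2 (adjusted p = 0.0550).

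The tests of fibroblasts, of scaling and of whole chromosomes that follow were chosen after the result was seen; those of blood or immune cells, of chance placement and of gene families were set out before the data were examined.

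Interferon-stimulated genes were higher in ZM-1 than in both ♂M lines. Scaling between arrays is argued against, since the median log2 difference of the interferon list was −1.15 after quantile normalization. Blood or immune cells, with a median of −0.26 for the mean of the ♂M lines minus ZM-1, and fibroblasts, with a median of −0.22, both fell between the values set as limits and stay open. Against ♂M-1 the fibroblast list had a median of 0.0116, past the limit set as counting against fibroblasts. By a further rule, a list with called members in both directions excludes nothing, and so fibroblasts were left open. In this list 3 members were called as lower in ♂M-1 (Dcn, Mmp2 and Twist2) and 1 as higher (S100a4). Dcn alone stayed called without ♂M-1 replicate 2 or ZM-1 replicate 1. Of the members, 18 of 21 lie above the median of all genes, which could hide a small share of other cells. An interferon response of the ZM-1 cells themselves also stays open and was not tested, and with 1 ZM line it may belong to the line or to its type.

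Called genes lay next to each other along chromosomes more often than random placement gave. Between ♂M-3 and ZM-1, 434 pairs of adjacent genes were called in the same direction, against a mean of 277 and a highest of 329 in 1000 placements matched on expression, which argues against chance placement. Without pairs of alike names, 365 pairs remained, against a mean of 262 and a highest of 311, so gene families named alike do not account for all of the excess in this comparison. For ♂M-1 against ZM-1 the 62 pairs (highest 40) fell to 39 without alike names (mean 19.4, highest 37), and for ♂M-1 against ♂M-3 the 107 (highest 69) fell to 93 (mean 45.3, highest 68). The largest departure of an autosome's median from the others was 0.0310 log2 units, which argues against gain or loss of a whole autosome. The X chromosome was not part of that test. Against ZM-1 its median lay further from that of the autosomes, by 0.0492 in ♂M-1 and 0.0553 in ♂M-3. Smaller gains or losses, strain variants and shared regulation stay open.

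Among the 12146 unnamed probe sets, 77 were called between ♂M-1 and ZM-1, 532 between ♂M-3 and ZM-1 and 93 between ♂M-1 and ♂M-3, and 31, 105 and 28 of them differed by at least 1 log2 unit. Of the called genes with more than 1 probe set, 10 of 51 between ♂M-1 and ZM-1, 25 of 164 between ♂M-3 and ZM-1 and 5 of 59 between ♂M-1 and ♂M-3 had another probe set with the opposite sign.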
